A study of Mus musculus with 2 samples.

How the data were processed

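Total RNA of sorted thymocytes was prepared with TRIzol, amplified by in vitro transcription with biotin labelling and stained with streptavidin-phycoerythrin, per the labels' protocols. One array was deposited here for each genotype. The deposited values are signal intensities per probe set on a linear scale, and GCOS version 1.4 is named in the submitters' processing notes. How GCOS was set is not given in the sources used here. A check of the values showed that both arrays have the same mean, 1000, after trimming 2% at each end, so they had been scaled to a common target before deposit. Scanner files and detection calls were not analysed here. The table holds 45101 probe sets, of which 64 are control probe sets and were left out of the gene comparison.

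Probe sets were named from the platform annotation supplied with the series, with symbols updated by gene identifier from the RefSeq table of the GRCm38.p6 assembly. Of all probe sets, some control ones included, 34958 have 1 gene symbol (34754 matched by identifier and 204 kept under their annotation name). Another 932 have several symbols and were not named, and 9160 non-control probe sets were not in the annotation and stayed unnamed. The annotation names no genome build, so no coordinates are given and the reference was used only for names and for which genes lie near Zbtb17, within 5 Mb on either side. Of 23 genes preset for the study's question, 20 had a named probe set.

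The following choices were made before the data were examined: the gene lists, the size rule, the floor, the rule for naming genes and the alternatives, except where a choice is said to have been added. The floor was the median of all non-control values on both arrays, 394, and values below it were raised to it before taking log2 of knockout over wild type. Each gene was read by its probe set with the highest mean signal. A gene was called measured if that mean was above the floor, and a difference was counted if its floored ratio was at least 2-fold with the brighter array above the floor. Where the dimmer array lay under the floor, the fold is a lower bound and is written as at least that fold. With 1 array per genotype there is no test of genotype. For each list, the median log2 ratio of its measured genes was placed among 10000 random lists of the same size, drawn from measured genes in 20 bins of mean signal. A percentile under 2.5 or over 97.5 is described as standing apart. This describes these 2 arrays only, and genes of a list are not independent. Of 30 lists with at least 3 measured genes, the sex-linked list left out, 16 stood apart, where 1.5 would by chance, and 12 did after Benjamini-Hochberg adjustment of the random-list shares over all 31 lists at 0.05. The Notch, ER stress, mature T cell and thymic stromal lists no longer stood apart after this adjustment. The sex-linked list joins genes that go opposite ways by construction, so its median and percentile are not used.

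Genes named in the text are Zbtb17 with all its probe sets, the 10 highest and 10 lowest ratios among named genes whose brighter array was at least 4 times the floor leaving out unnamed transcripts and genes with another probe set that differed 2-fold the other way, up to the 2 highest and 2 lowest members of each list past 2-fold, and the preset genes. Further list members given as examples, and second probe sets, were chosen after their values were seen.

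The spread of log2 ratios between measured probe sets of one gene is the only repeated measurement. It is given as the SD within a gene, in place of the SD of differences between pairs that had been planned. It covers noise within this pair of arrays, and also real differences between transcripts of a gene, but nothing between animals. The number of arrays limits the precision. On simulated arrays with that spread over 18193 genes, 194 of 200 genes changed 4-fold were recovered in the right direction. These 200 genes were drawn from those with a mean signal above 4 times the floor, so their recovery does not cover dimmer genes. Of 100 unchanged lists of 25 genes, 5 stood apart, a share that the percentile limits set by construction. Lists shifted by 0.4 and 0.8 on the log2 scale stood apart in 77 and 100 of 100 cases. Noise was simulated for each gene separately, so these list results do not cover lists whose genes vary together. The fraction of probe sets above the floor was 51.6% for the knockout and 48.4% for the wild type. The 3' over 5' signal ratio was 0.645 and 0.641 for Gapdh, and 1.60 and 2.06 for beta-actin, in the knockout and the wild type. Spiked hybridisation controls were brighter on the knockout array, with a median log2 ratio of 0.29 over 18 probe sets, and the 18S rRNA control probe sets were 1.83-fold to 2.17-fold brighter on the wild-type array. Poly-A controls, whether spiked or not being unstated, reached at most 556 and 437.

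Alternatives were median centring, quantile and loess normalization of the 2 arrays, a floor at the lower quartile or the 60th percentile, no floor with a pseudocount of 16, and the mean over a gene's measured probe sets. Others were only probe sets without the suffixes _x_at, _s_at or _a_at, and thresholds of 1.5-fold and 3-fold. Probe sets with these suffixes are called probe sets of shared sequence below. For _a_at, the sequence is shared between transcripts of 1 gene and not between genes. Leaving out X- and Y-linked genes was added after the data were seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.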

Results

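Gene expression was measured on 2 oligonucleotide arrays, 1 hybridised with RNA of Miz-1 knockout DN3 thymocytes and 1 with RNA of wild-type DN3 thymocytes, both from mice of the C57BL/6 background. Miz-1, encoded by Zbtb17, is a zinc finger transcription factor, and the knockout animals carry an allele that lacks its POZ domain, the part through which such factors bind one another and their partners. DN3 thymocytes are immature T cell precursors, sorted here as cells without lineage markers and CD44 but with CD25. At this stage the T cell receptor beta gene is rearranged, and cells that make a pre-T cell receptor pass the beta-selection checkpoint. The comparison asks how the expression pattern of DN3 cells differs when Miz-1 function is lost. There was 1 array per genotype and no replicate, so no value below has an error between animals and no difference was tested for significance. A difference of 2-fold or more is described by its size alone. Of 18193 genes with a probe set, 10770 had a mean signal above the floor of 394 and are called measured.

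Rpl22 was far below its wild-type level in the knockout. It encodes a ribosomal protein known to be needed for the development of alpha-beta T cells. Its brightest probe set read 2937 in the knockout and 68719.7 in the wild type, 23.4-fold lower, and the other 2 probe sets were 10.8-fold and at least 14.9-fold lower. Its paralog Rpl22l1 read 12186 and 13372, a log2 ratio of -0.13. The targeted gene Zbtb17 was 2.23-fold lower by its brighter probe set, with a signal of 1361 in the knockout against 3042 in the wild type. The second Zbtb17 probe set read 610 against 47.6, in the opposite direction and with a mean below the floor. The positions of these probes relative to the deleted part are not given in the sources used here, so Zbtb17 does not check the genotype labels. By the size rule 779 genes were at least 2-fold higher in the knockout and 608 at least 2-fold lower. Where several probe sets of 1 gene were measured, their log2 ratios spread with a root mean square SD of 0.57 over 4514 genes. Arrays simulated with that spread alone gave 829 such genes among 17993 unchanged ones, so single genes near 2-fold are not distinguishable from measurement noise. The spread came from probe sets with a mean above the floor and was applied to dimmer ones too. Their noise may differ, so 829 is not an exact count of what noise would give.

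**Figure D1:**
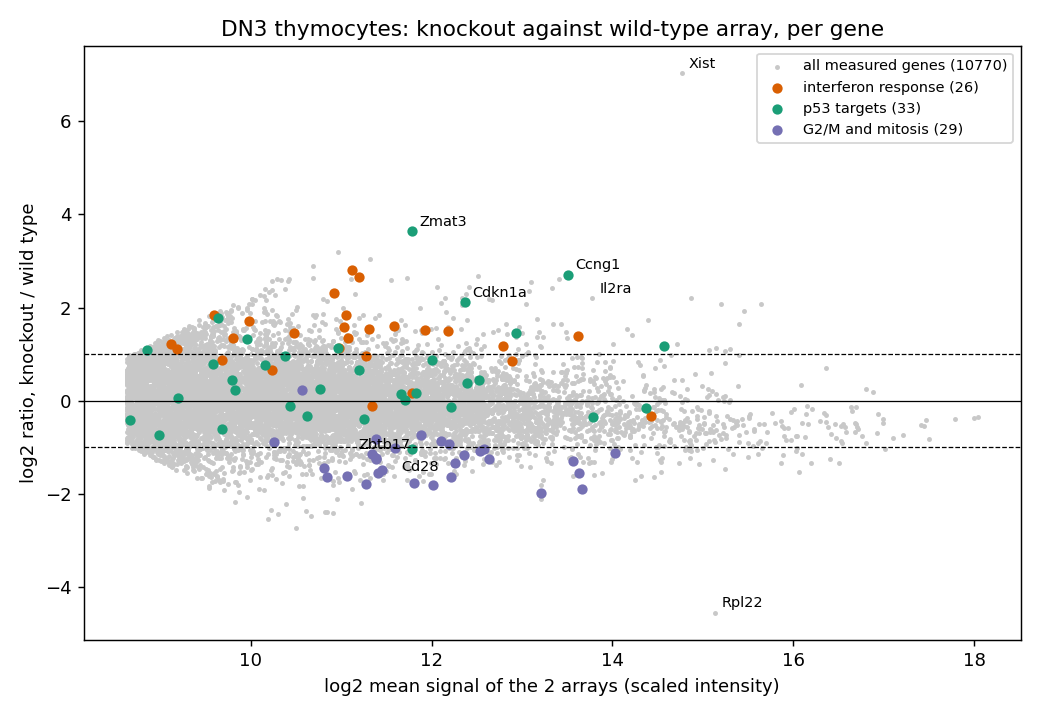
Each point is a measured gene, with the log2 of its mean signal on both arrays on the x axis and its log2 ratio of knockout over wild type on the y axis, 1 array per genotype. Dashed lines mark 2-fold, and coloured points are 3 gene lists: interferon response genes lie mostly above the upper line, mitosis genes mostly below the lower one, and Xist (7.03) and Rpl22 (-4.55) lie at the extremes.

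Genes activated by the tumour suppressor p53 were higher in the knockout as a group. Of 33 measured p53 targets, 9 were at least 2-fold higher and 1, Ckap2, was 2.05-fold lower. Zmat3, an RNA-binding p53 target, was 12.5-fold higher (6517 against 523), Ccng1, a cyclin family gene, 6.51-fold higher (20199 against 3100.5), and Cdkn1a, the cell cycle inhibitor p21, 4.34-fold higher (8627 against 1987). All 3 Ccng1 probe sets gave log2 ratios between 1.86 and 2.70. The death genes Pmaip1 (Noxa) and Bbc3 (Puma) were at least 3.43-fold and 2.52-fold higher, and Psrc1, Trp53inp1, Ercc5 and Epha2 were the other members past 2-fold. Mdm2, the ubiquitin ligase that limits p53, differed by less than 2-fold, with log2 ratios of 0.66 and -0.01 for its 2 measured probe sets. The median log2 ratio of the list was 0.39, at the 99.93rd percentile of 10000 random lists of the same size and expression. Without the members that also stand in another list it was 0.20, at the 93.4th percentile, inside the middle 95% of random lists.

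The BCL2 family, which sets the threshold for cell death, did not move in a single direction. Among 9 measured pro-apoptotic members, Pmaip1 and Bbc3 were higher while Bid was 2.47-fold and Bnip3 2.17-fold lower, and the list's median log2 ratio was -0.63 (0.665th percentile) with a mean of -0.12. Among 4 measured anti-apoptotic members, Bcl2l2 was 2.93-fold higher. The survival gene Bcl2 read 7212 against 3773 by its brightest probe set, a log2 ratio of 0.93, and its 5 probe sets ranged from 0.93 to 1.99. Bcl2l1 had a log2 ratio of -0.38. The median of these 4 genes was 0.94, at the 99.7th percentile. With fewer than 10 genes in each list, either median rests on a few genes, and neither list stood apart under all settings.

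Genes of cell division were lower in the knockout. Of 29 measured G2/M and mitosis genes, 23 were at least 2-fold lower and none was 2-fold higher, with a median log2 ratio of -1.25, lower than in all 10000 random lists. Cdca8, a subunit of the chromosomal passenger complex, was 3.96-fold lower, although its 3 probe sets ranged from -1.99 to -0.52, and Ube2c, a ubiquitin-conjugating enzyme that acts in mitosis, was 3.73-fold lower (5487 against 20451). The proliferation marker Mki67 was 2.93-fold lower and the mitotic kinase Plk1 3.42-fold lower. Of 29 measured DNA replication and S phase genes, 9 were at least 2-fold lower, with a median of -0.73, again lower than in all random lists. Cdc6, which loads the replicative helicase, was 2.84-fold lower, and the reductase subunit gene Rrm2 was 2.38-fold lower. Ccne1 was 2.46-fold lower by its brighter probe set but had a log2 ratio of 0.57 by the other. Both medians were the same in direction and stood apart in the 8 alternative settings. The S phase median was -0.59 under quantile and -0.55 under loess normalization.

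Genes of growth metabolism lay on the same side. Of 14 measured glycolysis genes, 5 were at least 2-fold lower and none was 2-fold higher, with a median log2 ratio of -0.68 (0.02nd percentile). Hk2, which phosphorylates glucose, was 2.64-fold lower, Pkm (pyruvate kinase) 2.49-fold lower and Ldha (lactate dehydrogenase) 2.17-fold lower. Of 24 measured nucleolar and MYC-responsive genes, 5 were at least 2-fold lower, among them Rrp9 at least 5.09-fold, Nme1 3.48-fold and the spermidine synthase gene Srm 2.49-fold, with a median of -0.65 (0.03rd percentile). The median of these MYC-responsive nucleolar genes was -0.38 under quantile and -0.36 under loess normalization. That of the glycolysis genes was -0.48 under quantile and -0.47 under loess normalization. Without probe sets of shared sequence, which left 7 measured glycolysis genes, it was -1.12. Myc itself had a log2 ratio of -0.38. Ribosomal protein genes, with Rpl22 counted among them, were not set apart as a list in the deposited values. Of 45 measured, 42 had a negative ratio, but their median of -0.49 lay at the 8.8th percentile. Random lists of equally bright genes, which may hold ribosomal protein genes too, also had a median of -0.39. Under quantile and loess normalization, which remove a trend with intensity, the median of the ribosomal protein genes was -0.06 and -0.01. Many of these genes are very bright, so such a step may also remove a real shift of theirs. These values therefore do not tell a trend from a shift. The list stood apart with a floor at the lower quartile (1.76th percentile) and with the mean of probe sets (0.64th percentile). Besides Rpl22, Rps2 and Rpl14 were at least 2-fold lower, and Rpl39 was 2.03-fold higher.

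Genes induced by interferon were higher in the knockout. Of 26 measured interferon response genes, 19 were at least 2-fold higher and none was 2-fold lower, with a median log2 ratio of 1.37, higher than in all 10000 random lists. Oas1a, an oligoadenylate synthetase, was 6.96-fold higher (3880 against 557), Usp18, which removes ISG15 from proteins, 6.34-fold, and Oasl2 4.95-fold higher. The transcription factor genes Irf7 and Irf9 were 2.98-fold and 3.05-fold higher. MHC class I genes moved with them: 7 of 11 measured class I and antigen presentation genes were at least 2-fold higher, with a median of 1.04, above all random lists. Nlrc5, the transactivator of class I genes, was 6.23-fold higher, H2-K1 4.24-fold (82937 against 19556), H2-D1 4.23-fold and B2m 3.82-fold higher. H2-K1, H2-D1 and their relatives are near-identical copies whose probe sets can share signal. On the same array 3 of the 5 measured myeloid markers were at least 2-fold higher, Lyz1 8.19-fold, Lyz2 3.59-fold and Csf1r 2.28-fold. The median of the 5 was 1.19 (99.96th percentile), while 17 of 22 myeloid markers had a mean signal below the floor. The Lyz1 value came from a probe set that can cross-hybridise, its second measured probe set had a log2 ratio of 0.87, and the remaining one was at or below the floor on both arrays. Of the dendritic cell and MHC class II markers, none of the 5 measured differed by 2-fold, and Cd74 read 619 against 667.

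**Figure D2:**
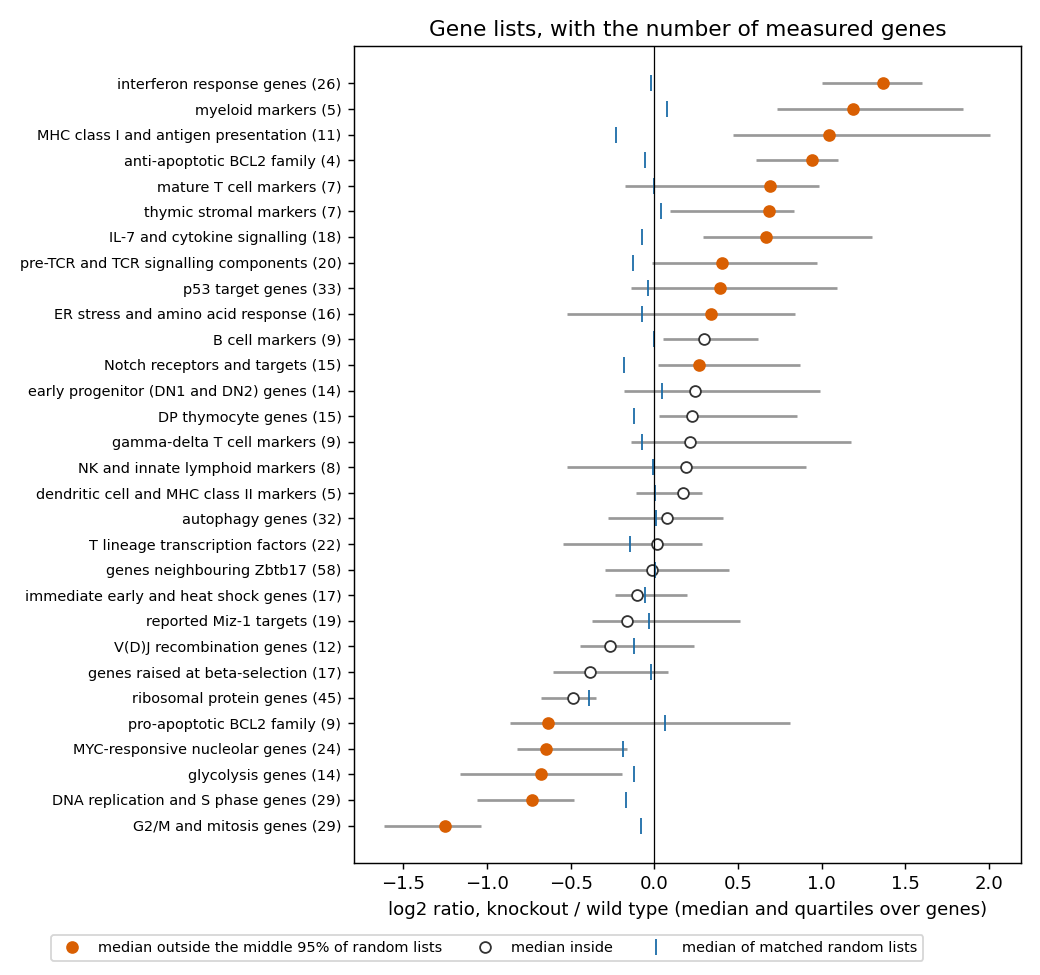
Each row is a gene list, with its number of measured genes in brackets. The dot is the median log2 ratio of knockout over wild type over the genes, the bar spans the quartiles and the blue tick is the median of matched random lists. Interferon response genes (1.37) lie at the upper end and mitosis genes (-1.25) at the lower end, and the sex-linked list is not drawn.

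Il2ra and some genes of Notch and cytokine signalling were higher. Il2ra, which encodes the CD25 used for the sort, was 4.61-fold higher (23017.9 against 4991.5), and both of its probe sets gave log2 ratios of at least 1.93. Cd44, absent from the sorted phenotype, was below the floor by its mean signal. Of 15 measured Notch receptors and targets, Dtx1 (5.09-fold) and Il2ra were more than 2-fold higher and Igf1r was 2.32-fold lower, the other 3 measured Igf1r probe sets being between -0.58 and -0.15. Dtx1 was read above the floor by 1 of its 2 probe sets. Notch1 read 57564 against 29223, a log2 ratio of 0.98, and the median of the Notch receptors and targets, 0.26, lay at the 98.4th percentile and was 0.63 with the mean of probe sets. After the adjustment over all lists, the Notch list did not stand apart. In the IL-7 and cytokine list 5 of 18 measured genes were at least 2-fold higher and Jak3 was 2.93-fold lower. The feedback inhibitor genes Socs2 and Cish were at least 5.96-fold and 3.61-fold higher and Socs3 had a log2 ratio of 1.59, although the 4 measured Socs2 probe sets ranged from -0.37 to 2.58. Il7r had a log2 ratio of 0.88 and Socs1 one of -0.31, and the list's median was 0.67, above all random lists.

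Few genes of pre-T cell receptor signalling passed 2-fold. Of 20 measured genes of pre-TCR and TCR signalling, Prkcq (3.40-fold), Cd3g (2.17-fold) and Cd3d (2.14-fold) were higher, none was 2-fold lower, and the median log2 ratio was 0.40 (99.91st percentile). Ptcra, which encodes the pre-T alpha chain, had a log2 ratio of 0.62 and Cd3e one of 0.08. The recombinase genes Rag1 and Rag2 had log2 ratios of -0.40 and 0.23, and the V(D)J recombination list lay at the 26.7th percentile, with Hmgb2 and Polm more than 2-fold lower. Of 17 measured genes that go up at beta-selection, 2 were at least 2-fold higher and 2 at least 2-fold lower. Cd28, a costimulatory receptor, was 3.08-fold lower (1499 against 4616) and the amino acid transporter gene Slc7a5 at least 2.06-fold lower, whereas Cd27 was 2.63-fold higher (3157 against 1199) and Ccnd2 2.67-fold higher. The 7 measured Ccnd2 probe sets had log2 ratios from 0.06 to 1.41. The list's median of -0.38 lay at the 2.62nd percentile, just inside the limit of 2.5, and was -0.16 for these genes raised at beta-selection without probe sets of shared sequence.

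**Figure D3:**
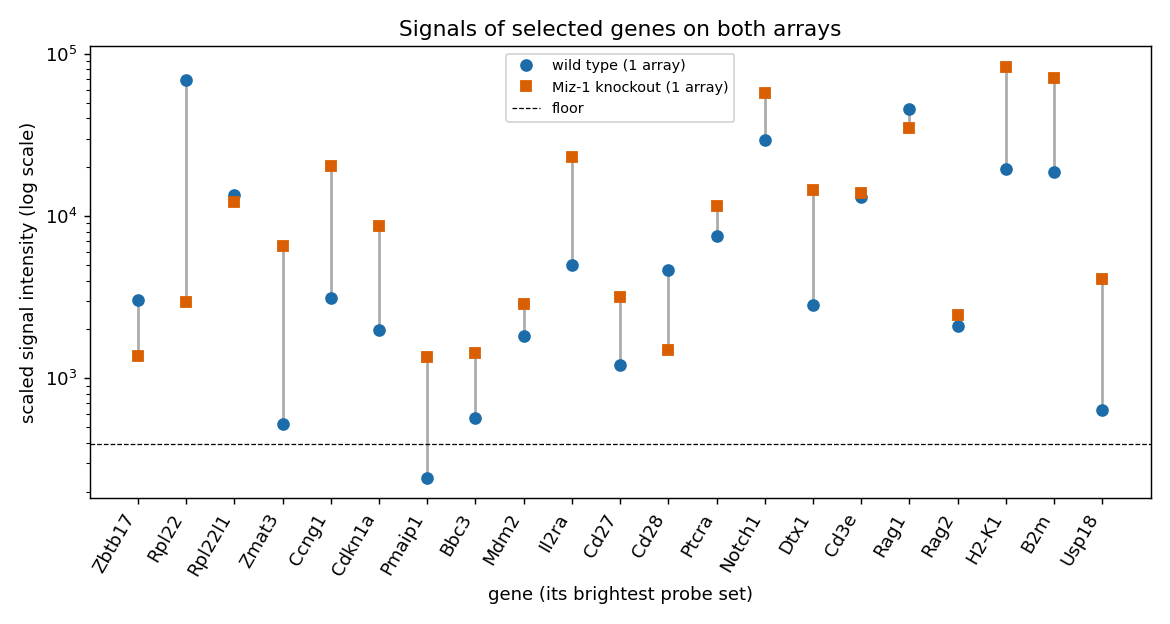
Signal intensity on a log axis for 21 genes, read by the brightest probe set of each, on the knockout array (squares) and the wild-type array (circles), with no replicates. The dashed line is the floor of 394. Rpl22 read 68719.7 in the wild type and 2937 in the knockout, while Zmat3, Ccng1 and Cdkn1a were higher in the knockout.

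Other T lineage lists did not stand apart from random lists in the deposited values. Of 22 measured T lineage transcription factors, Myb was 2.21-fold higher and Satb1 2.56-fold lower, with a median of 0.02. The 3 Myb probe sets had log2 ratios from 0.63 to 1.14, and 1 of the 4 measured Satb1 probe sets had one of 0.01. The preset list for double positive thymocytes (15 measured genes) holds genes also bright in these DN3 cells, such as Rag1. Its members thus do not mark that stage alone, and whether Cd53 marks it was not checked. The list's median was 0.23, and 0.42 under quantile normalization, where it stood apart, as under loess and the 60th percentile floor. In it the tetraspanin gene Cd53 was 5.43-fold higher. The chemokine receptor gene Ccr9 was 4.32-fold lower, with 1 of its 4 measured probe sets at 0.19. Of 14 measured early progenitor genes, 4 were at least 2-fold higher, among them Nfe2 (4.90-fold) and Mycn (3.58-fold), with a median of 0.25. Of 9 measured gamma-delta T cell markers, Trgv4, Maf and Cpa3 were more than 2-fold higher, with a median of 0.21. Of 19 measured genes reported as Miz-1 targets, Rpl22, Vps28 (2.35-fold) and Vamp4 (2.18-fold) were at least 2-fold lower, and Cdkn1a and Atg2a were at least 2-fold higher. The median of these reported Miz-1 targets, -0.16, lay at the 22.7th percentile. Its sign turned with the floor, to 0.28 at the lower quartile and 0.05 at the 60th percentile. The list was not split into activated and repressed targets, so its median does not show whether the targets responded. In the list of 32 measured autophagy genes, which does not hold Atg2a, Vamp4 passed 2-fold by 1 of its 3 measured probe sets and the median was 0.07. The 58 measured genes around Zbtb17 on its chromosome had a median of -0.02, with Znf41-ps and Sh2d5 2.70-fold and 2.53-fold higher and Fam131c and Rcc2 at least 2.33-fold and 2.31-fold lower. The heat shock genes Hspa1b and Hsph1 were 5.52-fold and 2.35-fold lower, with the 3 Hspa1b probe sets at -2.46, -1.15 and -0.55, while the list of immediate early and heat shock genes had a median of -0.10. In the ER stress list Ppp1r15a (3.05-fold) and Herpud1 (2.67-fold) were higher and the serine pathway genes Shmt2 (2.86-fold) and Psat1 (2.17-fold) lower, with a list median of 0.34 (98.2nd percentile), a list that did not stand apart under 5 alternatives. The second Herpud1 probe set had a log2 ratio of -0.64, and 2 of the 4 Shmt2 probe sets had log2 ratios of 0.28 and 0.15.

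Of the lists of markers of other cells, those of mature T cells and thymic stroma stood apart on the high side, as the myeloid markers did, but none of the 3 in all alternatives. The stromal list did not stand apart in 6 of 8, the mature T cell list had a median of 0.12 with a floor at the lower quartile, and the myeloid list one of 0.73 without probe sets of shared sequence. The 7 measured mature T cell markers (median 0.69, 98.3rd percentile) included Klf2, at least 2.67-fold higher, and Ctla4, 2.13-fold higher, and the 7 measured thymic stromal markers (median 0.69, 97.7th percentile) included Vim, which haematopoietic cells also express and whose 3 probe sets were 4.17-fold, 1.92-fold and 1.99-fold higher. Nkg7 and Xcl1 of 8 measured NK and innate lymphoid markers were at least 2-fold higher, with a list median of 0.19. That list stood apart with the 60th percentile floor (0.86) and without probe sets of shared sequence (0.85). Ighm and Cd22 of 9 measured B cell markers (median 0.30) were lower, with Ighm probe sets from -1.31 to 0.54. The 2 measured erythroid markers were globin genes with log2 ratios of 0.12 and 0.15. The sexes of the animals differed. Xist, transcribed from the inactive X chromosome of females, read 55300.0 in the knockout and 423 in the wild type, while the Y-linked genes Kdm5d and Eif2s3y were at least 4.52-fold and 3.64-fold lower in the knockout. Sex and genotype cannot be told apart with 1 animal or pool of each, so any autosomal difference listed here is open to both. Outside X and Y linkage 759 genes were higher and 590 lower.

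The remaining genes with the largest differences belonged to no list. Higher in the knockout were Fbp1, a gluconeogenic enzyme gene, at least 9.18-fold, Afdn, a junction protein gene, at least 7.44-fold, and the glycosyltransferase gene B4galnt2, 6.19-fold. Lower were Rab11fip4 at least 6.66-fold, Znhit3 at least 5.85-fold, Coq7, a ubiquinone synthesis gene, at least 5.40-fold, Tubb2a 5.30-fold, Gatad1 5.25-fold, Smim5 5.20-fold and Ndufaf6, an assembly factor gene of respiratory complex I, 5.19-fold. The second Tubb2a probe set had a log2 ratio of 0.15 near the floor, and the second measured Gatad1 probe set did not differ between the arrays.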

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

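The tests that weigh explanations in this part were chosen after the results were seen, while the alternative settings they draw on, and the percentile of the beta-selection list, were set before the data were examined. Among the probe sets that no single gene symbol covers, and which the gene comparison does not use, 112 were at least 2-fold brighter on the knockout array and 59 at least 2-fold dimmer, out of 1007 whose brighter array was at least 4 times the floor. The brighter ones are reported because they lie outside the gene comparison and exceed the level of the wild-type array. The highest log2 ratio was 3.53, and the lowest among the dimmer ones -3.49.

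Interferon response and MHC class I genes were higher in the knockout together. A scaling effect or a trend with intensity is argued against, since the lowest median of the interferon list over median centring, quantile and loess normalization was 1.33. RNA from myeloid or dendritic cells stays open: 8.33% of their markers, 3 of 36, were at least 2-fold higher, most others lay near or below the floor and decide nothing, and the sort for cells without lineage markers and CD44 but with CD25 would remove such cells. Sex, with a log2 ratio of 7.03 for Xist, and genotype, litter or infection of a single animal cannot be told apart with 1 array each.

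Mitosis and S phase genes were lower in the knockout. Scaling is argued against, since the highest median of the mitosis list over the 3 other scalings was -1.26. One candidate explanation is a smaller share of beta-selected, dividing cells inside the sorted gate, and the list of genes raised at beta-selection lay at the 2.62nd percentile, but at the 18.99th without probe sets of shared sequence. That stays open, because members of this list went both ways. Of 17 measured, 11 had a negative log2 ratio and 6 a positive one, with Cd28 3.08-fold lower and Cd27 2.63-fold higher. An effect of the genotype on the division of each cell, which the design names, was not tested separately from a change in the mixture.

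Rpl22 was far below the wild type. Scaling, floor and choice of probe set are argued against, since at most 2 measured genes had a lower log2 ratio than Rpl22 under the deposited values and the 8 alternatives. A single sequence variant under the probes is argued against by all 3 probe sets, of which the least changed had a log2 ratio of -3.44. Several variants, or a transcript with another end, stay open. Rpl22 lies on the same chromosome as Zbtb17 in the reference, but not among the genes within 5 Mb of it. The 58 measured genes within that distance had a median log2 ratio of -0.02, at the 42.55th percentile, with 5 at least 2-fold higher and 3 at least 2-fold lower. This median does not exclude variants that alter the signal of single genes in either direction. DNA of another strain around a targeted locus may carry more than 1 variant, and how far any such DNA reached here is not known. Loss of the transcript through loss of Miz-1 function is the biological hypothesis, and with 1 knockout array it was not tested.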

How the results depend on the processing

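The counts moved with the floor and the threshold. The genes at least 2-fold higher in knockout numbered 2682 with a floor at the lower quartile, 504 with one at the 60th percentile and 1872 with no floor and a pseudocount of 16, and the genes at least 2-fold lower in knockout numbered 2233 and 1473 at the first and last of these. A 1.5-fold threshold gave 2207 higher and 2031 lower, and a 3-fold one 156 and 80. Scaling changed neither count by over 1.5 times, but quantile normalization gave more lower than higher genes, 670 higher and 693 lower against 779 and 608 as deposited, and shared 630 and 547 of these. Of the 16 lists that stood apart, 9 did so under all alternatives: mitosis, S phase, interferon, MHC class I, IL-7 and cytokine, pre-TCR, Notch, glycolysis and MYC-responsive genes. Among these 9, the Notch list did not pass the Benjamini-Hochberg adjustment in the deposited values. The other 7 of the 16 no longer stood apart in some setting, and the cause was not tested unless the setting itself removes genes. The p53 list had a median of 0.20 without genes that also stand in another list, which leaves fewer genes, and it stood apart in the 8 other alternatives. Pro-apoptotic genes had -0.40 both with the 60th percentile floor and with the mean of probe sets. Without the shared-sequence probe sets, anti-apoptotic genes had 0.48 and myeloid markers 0.73. ER stress genes had 0.23 (quantile), 0.24 (loess), 0.34 (lower quartile floor), 0.28 (mean of probe sets) and 0.34 (no shared-sequence probe sets). Mature T cell markers had 0.12 with the lower quartile floor and 0.68 with the pseudocount. Thymic stromal markers had 0.61 (quantile), 0.75 (lower quartile floor), 0.41 (60th percentile), 0.72 (pseudocount), 0.38 (mean of probe sets) and 0.53 (no shared-sequence probe sets). Some lists came to stand apart: beta-selection genes at -0.42 (median centring), -0.53 (lower quartile floor) and -0.44 (60th percentile), though these genes raised at beta-selection had -0.29 under quantile and loess normalization and -0.16 without shared-sequence probe sets, double positive genes at 0.42 (quantile), 0.44 (loess) and 0.39 (60th percentile), NK markers at 0.86 (60th percentile) and 0.85 (no shared-sequence probe sets), and ribosomal protein genes at -0.50 (lower quartile floor) and -0.48 (mean of probe sets). Of 93 named genes, 81 passed 2-fold, 53 of these under all alternatives that gave them a value. Leaving out shared-sequence probe sets reversed Tubb2a (0.15), Ccne1 (0.57), Ccr9 (0.19) and Ighm (0.23). Of the genes higher in the knockout with several measured probe sets, 20.3% passed 2-fold in all of them, and of the genes lower 14.7%. No paired analysis was possible because each genotype has 1 array. Signal over background limits the rest: 284 of the higher and 168 of the lower genes were under the floor on the other array.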

Other observations

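The sets in this part, and their tests, were chosen after the data were seen. Most measured genes of mitochondrial ribosomal proteins and of the respiratory chain had a negative log2 ratio, and few passed 2-fold. Of 76 measured mitochondrial ribosomal protein genes, 60 had a negative log2 ratio, 5 were at least 2-fold lower and none was 2-fold higher, with a median of -0.45. Mrpl28 was 3.31-fold lower and Mrpl32 2.45-fold lower. Of 93 measured genes of respiratory chain subunits and their assembly, 76 had a negative ratio, 8 were at least 2-fold lower, among them Uqcrfs1 (2.67-fold), Uqcrq (2.35-fold) and Cox5a (2.13-fold), and 1, Cox6b2, was 2.86-fold higher, with a median of -0.47. Over the alternative settings the medians ranged from -0.48 to -0.29 and from -0.51 to -0.23. These genes were picked from 267 groups that share the start of a symbol, of which 24 stood apart where 13.4 would by chance, so their place among random lists is no test.

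Transcripts of the T cell receptor gamma locus were brighter on the knockout array. Trgv1 read 49216 against 10619, 4.63-fold higher, and the 3 Trgv4 probe sets were 3.13-fold, 3.36-fold and 4.95-fold higher. Segments of this family share sequence, so the probe sets are not independent and the segment is uncertain. The beta chain probe set of Trbv1 with the highest signal read 39773.5 against 40533, a log2 ratio of -0.03, and Trbv13-2 had a log2 ratio of 0.43. Of 11 measured Parp genes, 6 were at least 2-fold higher and none was 2-fold lower, with a median of 1.18, and several Parp genes are known to be induced by interferon.

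The difference in sex was not accompanied by a shift of the X chromosome. The 314 measured X-linked genes had a median log2 ratio of -0.05, at the 14.6th percentile, against 0.00 for 10450 autosomal genes. Kdm6a, which escapes X inactivation, was 3.64-fold higher in the knockout, while Kdm5c, Eif2s3x and Ddx3x, which also escape, had log2 ratios of 0.52, 0.46 and -0.40.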
